A study of Mus musculus with 6 samples.

How the data were processed

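The samples were thoracic spinal cords of newborn mice, 3 WT and 3 Myt1-/-, measured by RNA sequencing. Groups and replicate numbers come from the sample labels. The deposited table gives 1 TPM value per gene and sample, with 2 decimals, for 55487 Ensembl genes with symbols. Per the submitters' processing notes, RSEM, DESeq2 and the genome build GRCm38.p6 were used, without saying for which step; the aligner, the annotation release and any filter on reads are not given in the sources used here. TPM divide a gene's reads by its transcript length and scale each sample to the same total, so a gene's value falls when others rise. The column sums were between 993139 and 994687, which rounding does not account for, since it can move a sum by at most 277 TPM; the rest was not accounted for. The table holds no counts and no depth, so precision is taken only from the spread between samples. One column of per-sample values (1 in all) has no sample among the labels and was not used.

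Gene positions come from GENCODE M21 (GRCm38), which held 55141 of the 55487 gene IDs and lacked 346. Every pair of WT samples had a correlation across genes of log2(TPM + 1) between 0.965 and 0.970, every pair of null samples between 0.968 and 0.973, and pairs across groups between 0.962 and 0.975; genes are not independent replicates, and no pair held the same values. Mitochondrially encoded genes made up 11.3% of TPM in WT replicate 1 and 8.64% to 9.04% in the other samples.

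The test planned for counts could not be used on TPM. The fallback written with it was used instead: limma 3.58.1 in R 4.3.3, with a trend in the variance prior, on log2(TPM + 1), leaving out 39525 genes whose mean over the 6 samples was under 1 TPM and testing 15962. Genotype was the only term, p-values were two-sided and Benjamini-Hochberg adjusted, and a gene passed at an adjusted p under 0.05. Log2 changes are null minus WT on the log2(TPM + 1) scale, which understates the change of low genes, while folds are ratios of mean TPM. Intervals are 95% intervals from the same limma fit. The design, the alternatives, the rule for named genes and 37 gene lists were fixed before the data were examined.

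Of the lists 36 were tested; the list of Y-linked genes and Xist had 1 measured member. Members count as measured when they passed the filter. Each list was tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the 36 lists. Of the 36, 14 were called, 11 lower and 3 higher, of which 0 were called with an estimated correlation. The rotation test fry in limma called 1. Members were also adjusted over the list alone, with the same method. Differences between lists were taken as the difference of their mean log2 levels in each library, with an exact two-sided permutation test. The fit of list means on genotype and the Schwann cell mean was an ordinary linear model with 95% t intervals on 3 residual degrees of freedom. The named genes were Myt1, Myt1l and St18, up to 10 genes in each direction among those past an adjusted p of 0.05 (none passed) and up to 4 members per list with the smallest adjusted p; others named were chosen after their values were seen. Some genes that the rules name are not reported here, though they stay in every test and count. Where a list's symbol was not found in the table, older symbols were not searched.

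The alternatives fixed in advance and run were no variance trend, a pseudocount of 0.1, no filter except genes at 0 in every sample, a filter of at least 1 TPM in at least 3 samples, replicate number as a block, stricter thresholds, camera with an estimated correlation, fry, and leaving out each sample in turn. Added after seeing the data were median-ratio and upper-quartile scaling, nuclear protein-coding genes rescaled, robust empirical Bayes, array weights and protein-coding genes only. The labels share replicate numbers across groups without saying that a number marks a litter or batch.

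The fit was tested on simulated data of this comparison, 15962 genes drawn independently with the real means and spreads in 10 runs, each with 200 changed genes. It recovered 39.2% of genes changed 1.5-fold, 67.8% of those changed 2-fold and 91.3% of those changed 4-fold. There were 66 false calls over the 10 runs. These folds were set on the log2(TPM + 1) scale, where the same fold is a larger change in TPM for low genes. Each gene's estimated spread was taken as its true spread, so recovery in the real data may be lower. A simulated list of 20 genes shifted by -0.5 was called by camera in 10 of 10 runs and an unshifted list in 0. Members of real lists can move together, with an estimated correlation of 0.366 in the myelinating oligodendrocyte list. Independent draws therefore do not test camera's calls for such lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.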

Results

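RNA was sequenced from the thoracic spinal cord of newborn mice (postnatal day 0), from 3 wild-type samples (WT) and 3 samples lacking both working copies of Myt1 (Myt1-/-, below called the null). Myt1 encodes a zinc finger transcription factor of the nervous system, and the comparison asks which genes depend on it while oligodendrocytes, the myelin-forming cells of the central nervous system, are maturing. The values were TPM (transcript abundance scaled for transcript length and for the total of the sample) for 55487 genes, with 22368 to 23000 genes above 0 in a sample. TPM do not carry the number of reads, so the depth of each sample is unknown and no counting interval is given. Xist, which is transcribed from the inactive X chromosome, lay between 65.7 and 108 TPM in all 6 samples, and Ddx3y, Uty, Eif2s3y and Kdm5d, which lie on the Y chromosome, did not exceed 0.10 TPM in any. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples. The mean log2 level of sensory ganglion genes lay 0.033, -0.60 and 0.57 from the WT mean in the WT samples. In the null samples it lay at -0.34, -0.40 and -1.82, and that of skeletal muscle genes at -0.84, -0.50 and 2.06. These values argue against all 3 samples of a group being repeats of a single RNA, but do not show separate animals.

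Myt1 itself (ENSMUSG00000010505, chromosome 2, 181763332 to 181827797, plus strand, GRCm38) was measured at 11.54, 11.53 and 13.61 TPM in the WT samples and at 6.14, 5.36 and 5.28 TPM in the null samples. Its mean was 12.2 ± 1.20 TPM in WT and 5.59 ± 0.475 TPM in the null (SD, n = 3 each), which is 2.19-fold lower and 45.7% of the WT level. Every null sample lay below every WT sample, so the labels and the targeted gene go the same way. A value for the whole gene does not separate deleted exons from those still transcribed. The level that remained does not by itself show loss of both copies, which rests on the labels. The change was -1.0 on the log2(TPM + 1) scale (SE 0.11), with an adjusted p of 0.140 by limma over all genes tested and of 0.000158 adjusted over the list alone, the list being Myt1 and its paralogs. The paralogs were Myt1l, at 68.0 ± 8.22 TPM in WT and 73.5 ± 2.96 TPM in the null, and St18, at 3.89 ± 1.39 and 3.23 ± 0.243 TPM; neither passed the test. As a list, Myt1 and its paralogs had an adjusted p of 0.0766 by limma's camera. It was 0.0282 without WT replicate 2 and 0.416 without WT replicate 3, where the median was 0.040. The list holds the targeted gene itself, so these values do not test the paralogs alone.

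Across the transcriptome, no gene of the 15962 tested passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 1189 genes, 690 higher and 499 lower in the null. Without WT replicate 1 the higher genes numbered 512 of 1260. After median-ratio scaling they numbered 542 of 1207, and after upper-quartile scaling 583 of 1219. In 2280 genes (14.3%, against 10% by chance) the samples of the groups did not overlap, with 858 below and 1422 above every WT sample. The smallest adjusted p, 0.0798, belonged to Gm43493, a processed pseudogene at 10.42, 6.54 and 14.27 TPM in the WT samples and listed at 0 in all 3 null samples; pseudogenes share reads with their parent genes, so this value is uncertain. One library decided small counts of calls: 7 genes passed without WT replicate 2, and 1 gene passed without WT replicate 3 (Bcas1), without null replicate 1 (Gm44389) and without null replicate 2 (Rpl35a-ps4). The gene groups that follow were fixed beforehand, and a member is said to rise or fall where its limma p passed 0.05 adjusted over the list alone. This adjustment does not correct for the 36 lists tested, so a lone passing member of a list can be a chance result. No member passed when adjusted over all genes.

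**Figure D1:**
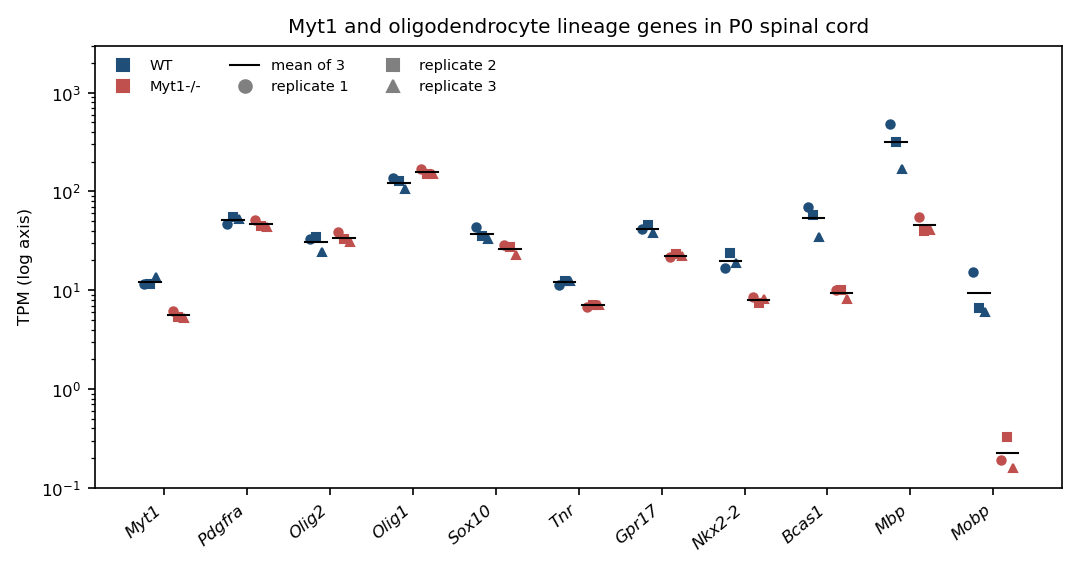
TPM (log axis) of Myt1 and 10 oligodendrocyte lineage genes in each of the 3 WT and 3 Myt1-/- libraries, with bars at the mean of 3. Mbp, Mobp, Bcas1 and Nkx2-2 lie lower in every null library than in any WT library, Pdgfra and Olig2 overlap, and Olig1 averages 123 TPM in WT and 156 TPM in the null.

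Genes of myelin and of mature oligodendrocytes were lower in the null cord. Of 22 measured members of the myelinating oligodendrocyte list, 14 fell, none rose and 8 did not pass. Mobp, which encodes a myelin-associated basic protein, fell from 9.29 ± 5.11 to 0.227 ± 0.0907 TPM (SD, n = 3 each), 41.0-fold lower. Its null values were near the floor, at 0.19, 0.33 and 0.16 TPM, so the size of this fold is uncertain. Mbp, encoding myelin basic protein, fell from 320 ± 155 to 45.4 ± 8.58 TPM, 7.05-fold lower. Myrf, a transcription factor that drives myelin genes, fell 5.30-fold to 1.16 ± 0.498 TPM.

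Among the members that fell were 3 enzymes of myelin glycolipids, which were not tested as a group. Gal3st1, the sulfotransferase that makes sulfatide, fell from 18.9 ± 1.10 to 12.7 ± 0.240 TPM. Ugt8a, which makes galactosylceramide, was 3.24-fold lower, and Fa2h, which hydroxylates myelin fatty acids, 3.63-fold lower. Mag, Tmem88b, Cnp, Sirt2, Mal, Nfasc and Cldn11 also fell, by between 4.91-fold for Mag and 1.37-fold for Cldn11. Mog, which is found on the outer face of myelin, was at 2.18 TPM in WT and 2.21 TPM in the null, with a log2 difference of 0.04 and a 95% interval of -0.44 to 0.51.

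The median member of the myelinating list changed by -0.66 on the log2 scale, and 14 members lay below every WT sample. The log2 changes were -2.96 (SE 0.32) for Mobp and -2.68 (SE 0.36) for Mbp. By limma, their p adjusted over the list alone was 0.00113 and 0.00163, and their adjusted p over all genes was 0.140 and 0.231. All 14 but Cldn11 passed with any 1 library left out; of these 6 fits, Cldn11 passed in that without WT replicate 1 alone. Camera gave the list an adjusted p of 2.06e-21 at its preset correlation, and an adjusted p of 0.317 with an estimated correlation. The WT libraries differed among themselves, with Mbp at 477.4, 313.8 and 167.9 TPM, and the Schwann cell list, which shares myelin biology, was also lower in the null, with a median of -0.51.

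Genes of committed and newly forming oligodendrocytes were lower as well. Of 15 measured members, 9 fell, none rose and 6 did not pass. Gpr17, a receptor that marks committed precursors, fell from 41.9 ± 3.64 to 22.2 ± 0.869 TPM (SD, n = 3 each), 1.89-fold lower. Bcas1, which marks oligodendrocytes that begin to myelinate, fell from 53.9 ± 17.4 to 9.44 ± 1.11 TPM, 5.71-fold lower. Nkx2-2, a homeodomain factor needed for oligodendrocyte differentiation, fell from 19.9 ± 3.61 to 8.04 ± 0.552 TPM, 2.47-fold lower, and Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, fell from 4.58 ± 2.20 to 0.207 ± 0.10 TPM, 22.1-fold lower. The null values of Enpp6 were near the floor, at 0.11, 0.31 and 0.20 TPM, so the size of its fold is uncertain.

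Tns3, Kif19a, Lims2, Itpr2 and Cnksr3 also fell, by between 1.39-fold for Tns3 and 2.50-fold for Lims2. Zfp488, a transcription factor of the same stage, averaged 4.75 TPM in WT and 3.48 TPM in the null without passing. Zfp536 was at 11.5 and 11.3 TPM. The median member changed by -0.51, and 11 members lay below every WT sample while 1, Rras2, lay above. By limma, the p adjusted over the list alone was 0.000206 for Gpr17, 0.000264 for Bcas1, 0.000320 for Nkx2-2 and 0.00106 for Enpp6, and the adjusted p over all genes was 0.109, 0.140, 0.146 and 0.301. Of the 9, 6 passed with any 1 library left out. The list lost Cnksr3 without WT replicates 1 or 2 or null replicates 2 or 3, Itpr2 without WT replicate 2 or null replicate 3, and Lims2 without null replicate 3. Camera gave an adjusted p of 2.96e-15 for the list, against an adjusted p of 0.119 with an estimated correlation. This was the only list of 36 called by fry, a rotation test in limma of whether members move one way on balance (adjusted p = 0.0128). The Schwann cell list moved in the same direction here too, by -0.51 at its median.

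Genes of oligodendrocyte precursors went both ways. Of 19 measured members 4 fell, 1 rose and 14 did not pass. Tnr, encoding the matrix glycoprotein tenascin-R, fell from 12.1 ± 0.616 to 7.02 ± 0.178 TPM (SD, n = 3 each), and Matn4, encoding a matrilin, from 15.9 ± 0.218 to 9.13 ± 1.02 TPM. Sox10, a transcription factor of the lineage, fell from 37.2 ± 5.50 to 26.3 ± 3.09 TPM, and Gpr37l1 was 1.87-fold lower. Olig1, a bHLH factor of the lineage, rose from 123 ± 14.7 to 156 ± 10.1 TPM, 1.27-fold higher.

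Pdgfra, the growth factor receptor that defines precursors, did not pass: it was at 51.6 ± 4.35 TPM in WT and 46.9 ± 3.92 TPM in the null (SD, n = 3 each), with a log2 difference of -0.14 and a 95% interval of -0.34 to 0.07. Olig2 differed by 0.15 (95% interval -0.20 to 0.50) and Cspg4, which encodes the NG2 proteoglycan, by 0.11 (95% interval -0.24 to 0.45). By limma, the p adjusted over the list alone was 0.00155 for Tnr and for Matn4, 0.0425 for Sox10 and for Olig1, and 0.0464 for Gpr37l1. Tnr and Matn4 passed with any 1 library left out. The count of members that fell was 2 without WT replicate 2 and without null replicates 1, 2 or 3, and of these 6 fits Olig1 passed in that without WT replicate 1 alone. The list median was -0.037 (-0.13 to -0.024 with 1 library left out), with an adjusted p of 0.00165 by camera and an adjusted p of 0.566 with an estimated correlation. The Schwann cell list, which also holds Sox10, was lower by -0.51 at its median.

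The lists were compared directly, by the difference between their mean log2 levels in each library. Committed minus precursor was -0.76 ± 0.017 in WT and -1.34 ± 0.021 in the null (SD, n = 3 each), a change of -0.58 (exact permutation p = 0.1). Myelinating minus precursor changed by -0.78, from -0.60 ± 0.25 to -1.38 ± 0.030 (exact permutation p = 0.1). Myelinating minus committed changed by -0.20, less than its SD of 0.27 in WT (exact permutation p = 0.1). The mean log2 level of the committed list was 4.01 ± 0.10 in WT and 3.27 ± 0.04 in the null (SD, n = 3 each), and that of the myelinating list 4.17 ± 0.28 and 3.22 ± 0.05. An exact two-sided permutation test of 3 samples against 3 cannot go below 0.1, so it could not reach 0.05.

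**Figure D2:**
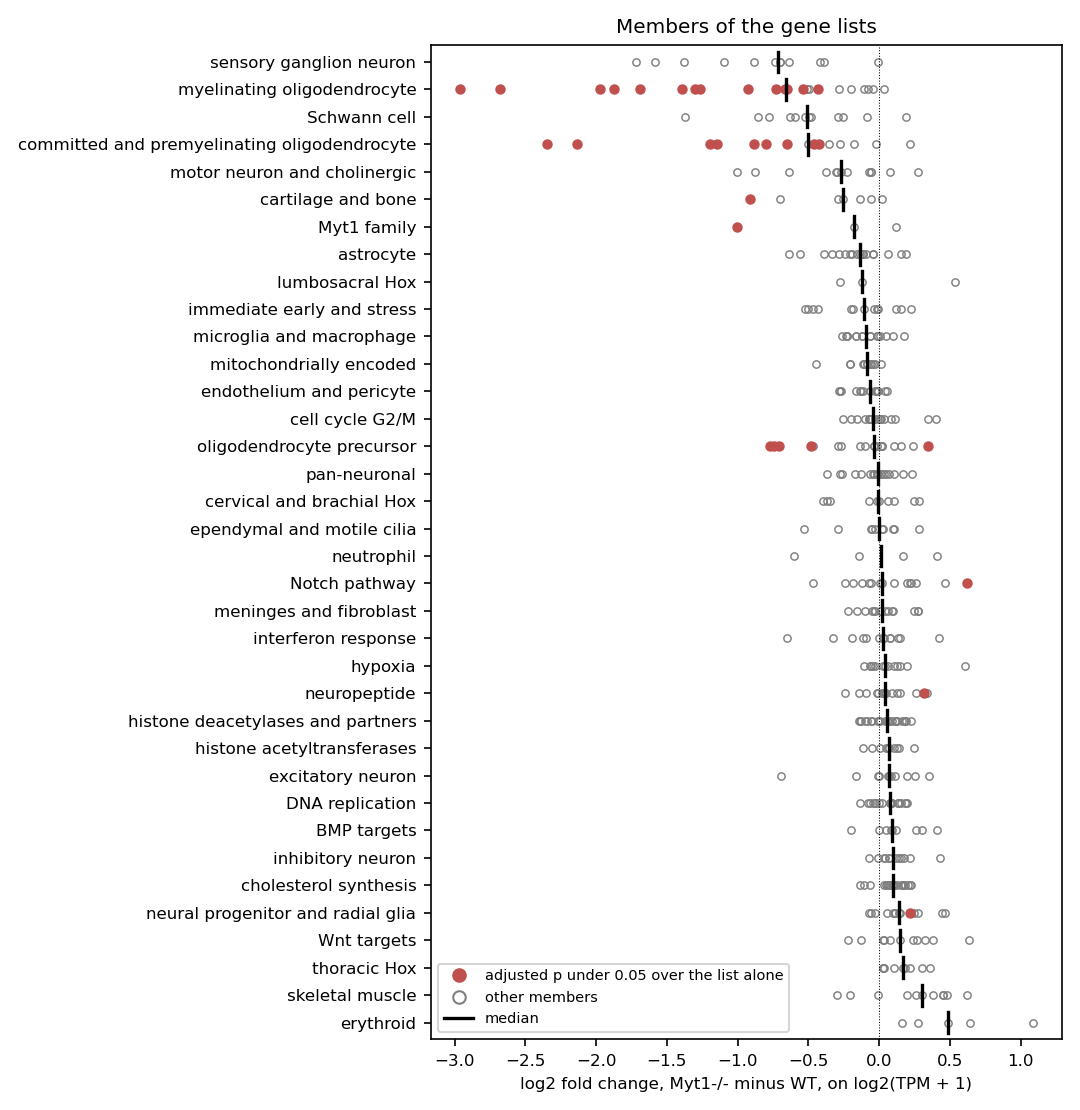
Log2 change (null minus WT, log2(TPM + 1) scale) of each measured member of the 36 gene lists; red points passed 0.05 adjusted over the list alone and black marks are list medians. The medians of the myelinating (-0.66) and committed (-0.51) lists lie below 0 with many red members, and the Schwann (-0.51) and sensory ganglion (-0.72) medians lie as low with none.

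Among the other neural cell types, camera at its preset correlation called astrocyte and motor neuron markers lower as lists and progenitor markers higher. With an estimated correlation none of these was called (adjusted p = 0.566, 0.400 and 0.364), and single members mostly did not pass. The astrocyte list (19 measured, none past) had a median of -0.13. Among its leading members were Glul, encoding glutamine synthetase, at 375 ± 22.3 TPM in WT and 326 ± 17.3 TPM in the null (SD, n = 3 each), and Aldoc, an aldolase of astrocytes, at 655 ± 104 and 516 ± 16.9 TPM. The motor neuron and cholinergic list (13 measured, none past) had a median of -0.27, led by Slc18a3, the vesicular acetylcholine transporter, at 25.1 ± 3.16 and 19.0 ± 1.02 TPM. The sensory ganglion list, which shares Isl1 with it, was lower too (median -0.72). Both lists had their lowest mean in null replicate 3, at -0.49 and -1.82 from the WT mean. Like Isl1, the motor neuron members Prph and Isl2 were highest in WT replicate 3 (277.55 and 15.31 TPM). They were lowest in null replicate 3 (67.12 and 1.44 TPM). Slc18a3 did not follow this order, with its lowest WT value, 22.51 TPM, in WT replicate 3. How much of the motor neuron list's fall comes from ganglion was not tested. The progenitor and radial glia list (15 measured) had a median of 0.14, and Fabp7, a fatty acid binding protein of radial glia, rose 1.16-fold from 1614 to 1879 TPM.

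Camera's adjusted p for these lists was 1.41e-05 for astrocytes, 0.000188 for motor neurons and 0.0155 for progenitors. The progenitor list lost its call without WT replicate 3 (adjusted p = 0.111) and without null replicate 1 (adjusted p = 0.0909), and Fabp7 (limma adjusted p = 0.0197, adjusted over the list alone) passed in 1 of the 6 fits that left out a library, that without WT replicate 1. Among neuropeptides (16 measured, median 0.042, camera adjusted p = 0.563) Pdyn, encoding prodynorphin, rose from 39.3 ± 2.66 to 49.0 ± 1.00 TPM and the other 15 did not pass. Pdyn's p by limma was 0.0312 adjusted over the list alone, and it passed in 1 of the 6 fits that left out a library, that without WT replicate 1. Pan-neuronal genes (18 measured) had a median of -0.010 and a camera adjusted p of 0.197, or 0.0414 without WT replicate 2. The neurofilament genes Nefl, Nefm and Nefh averaged 818, 743 and 85.5 TPM in WT and 680, 611 and 66.0 TPM in the null. Members of this list went both ways, with 4 below and 1 above every WT sample, and none passed. No member passed among inhibitory neuron genes (12 measured, median 0.097, camera adjusted p = 0.174), excitatory neuron genes (12 measured, median 0.072, adjusted p = 0.363) or ependymal and motile cilia genes (10 measured, median -0.0032, adjusted p = 0.728).

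Histone deacetylases and their partners were of interest because the study's title ties Myt1 to Hdac1, and their transcripts were little different. Of 23 measured members none passed, and the median was 0.054. Hdac1, which removes acetyl groups from histones, was at 42.1 ± 5.37 TPM in WT and 45.9 ± 3.77 TPM in the null (SD, n = 3 each), with a log2 difference of 0.13 and a 95% interval of -0.13 to 0.38. Hdac2, its close paralog, was at 157 ± 2.66 and 179 ± 6.72 TPM (limma adjusted p = 0.0928, adjusted over the list alone). Camera's adjusted p was 0.586 for this list and 0.310 for histone acetyltransferases (10 measured, none past, median 0.068). Transcript levels say nothing of where the enzymes act or of histone marks, which were not analysed here.

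Of the signalling lists, the Notch pathway (15 measured) had 1 member past the test. Dll3, a divergent Notch ligand, rose from 6.18 ± 0.197 to 10.1 ± 0.991 TPM (SD, n = 3 each), 1.63-fold higher, with a p of 0.00972 by limma adjusted over the list alone, which it lost without null replicates 2 or 3 (highest p 0.0692). The list's median was 0.020 while camera's direction was down (adjusted p = 0.991). Wnt targets (11 measured, median 0.15, camera adjusted p = 0.174) included Rnf43, a feedback inhibitor of Wnt signalling, at 1.19 ± 0.163 TPM in WT and 2.42 ± 0.348 TPM in the null, without any member past the test. BMP targets (9 measured, median 0.089, camera adjusted p = 0.234) had none past either.

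Cholesterol synthesis, which feeds myelin membranes, was slightly higher as a list (21 measured, none past, median 0.098), with Hmgcs1 at 348 ± 26.5 TPM in WT and 387 ± 4.11 TPM in the null (SD, n = 3 each). Its camera adjusted p of 0.0360 became an adjusted p of 0.810 with an estimated correlation, 0.412 without WT replicate 1 (median 0.030), 0.238 without null replicate 1 and 0.0565 with replicate number as a block. Proliferation genes showed no member past the test: G2/M genes (20 measured) had a median of -0.040 and a camera adjusted p of 0.527, and DNA replication genes (21 measured) a median of 0.079 and an adjusted p of 0.580. Without WT replicate 1 the G2/M list had a median of -0.17 and an adjusted p of 0.00163. Immediate early and stress genes (13 measured, median -0.10, camera adjusted p = 0.0801) passed as a list without WT replicate 1 (0.0265) and without null replicate 1 (0.00833). Hypoxia genes (13 measured) had a median of 0.042 and an adjusted p of 0.931. Interferon response genes (13 measured) had a median of 0.029 with camera pointing down (adjusted p = 0.633), and without WT replicate 3 a median of -0.30 (adjusted p = 0.00791). Mitochondrially encoded genes (13 measured, median -0.082, camera adjusted p = 0.0155) lost their call with an estimated correlation (adjusted p = 0.696), without null replicate 2 (0.0817) or 3 (0.0513) and without WT replicate 1, where the median was 0.067 (adjusted p = 0.0841).

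Genes of tissues that adjoin the cord varied widely between libraries of the same genotype. Schwann cell genes (12 measured, none past) had a median of -0.51, and Sox10, at 37.2 ± 5.50 TPM in WT and 26.3 ± 3.09 TPM in the null (SD, n = 3 each), missed the threshold in this list with a limma adjusted p of 0.0506, adjusted over the list alone. Sensory ganglion genes (12 measured, none past) had a median of -0.72, and Avil, a ganglion marker, was at 20.23, 7.85 and 40.19 TPM in the WT samples and at 14.82, 10.99 and 0.14 TPM in the null samples. Skeletal muscle genes (11 measured, none past) had a median of 0.30, with Acta1, skeletal actin, at 44.35 TPM in null replicate 3 and 3.73 to 22.51 TPM in the other libraries. Cartilage and bone genes (7 measured) had a median of -0.26, and Col11a2, a cartilage collagen, fell from 7.53 ± 2.24 to 3.46 ± 0.573 TPM.

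**Figure D3:**
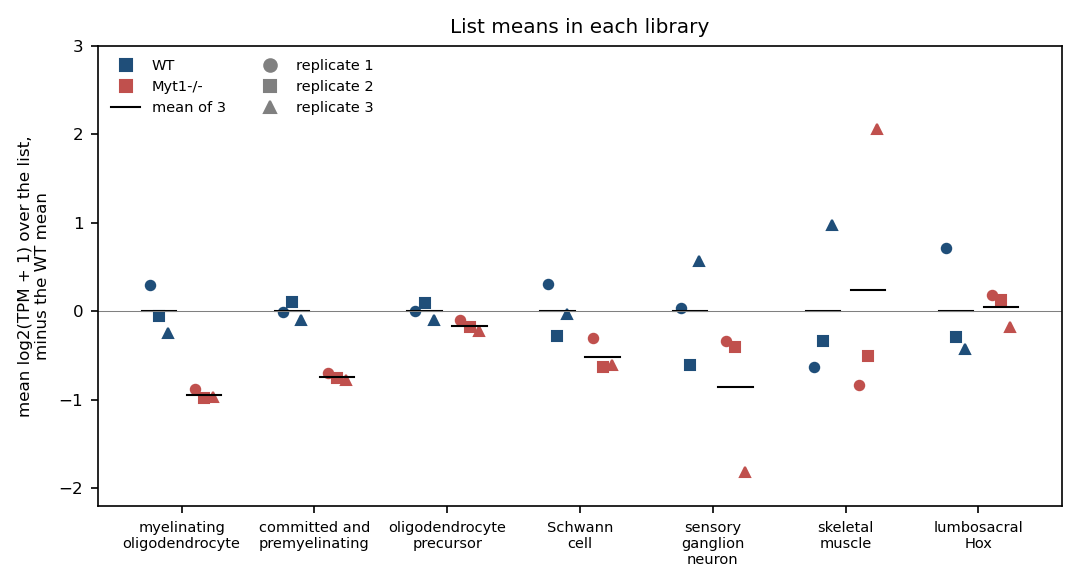
Mean log2(TPM + 1) of 7 gene lists in each library, minus the WT mean of that list. The myelinating and committed lists lie below every WT library in all 3 null libraries, while the sensory ganglion mean is -1.82 and the muscle mean 2.06 in null replicate 3.

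Camera's adjusted p was 3.93e-06 for the Schwann list, 1.31e-05 for the sensory list, 0.991 for the muscle list and 0.0151 for the cartilage list, and with an estimated correlation the adjusted p was 0.400, 0.566, 0.995 and 0.566. Without null replicate 3 the muscle median was -0.59 (adjusted p = 0.000602) and the cartilage list lost its call (median -0.31, adjusted p = 0.0505), as it did without WT replicate 3, where its median was -0.026 (adjusted p = 0.308). Col11a2 had a p of 0.0275 by limma adjusted over the list alone, and did not pass without WT replicate 3 or without any 1 of the null replicates. Among blood and vessel cells, microglia and macrophage genes (16 measured, none past) had a median of -0.095 and a camera adjusted p of 0.0323, with an adjusted p of 0.696 at an estimated correlation, of 0.538 without WT replicate 2 (median -0.023) and of 0.163 without null replicate 3 (median -0.050). Endothelium and pericyte genes (15 measured, none past) had a median of -0.066 and a camera adjusted p of 0.00582, and an adjusted p of 0.317 with an estimated correlation; Pecam1, an endothelial adhesion molecule, was at 22.1 ± 1.23 and 18.0 ± 0.450 TPM. Meningeal genes (14 measured, median 0.023, camera pointing down with adjusted p = 0.784) had a median of -0.27 without WT replicate 1 (adjusted p = 3.54e-05). Erythroid genes (5 measured, median 0.49, adjusted p = 0.542) had a median of 1.30 without WT replicate 3 (adjusted p = 0.00801), and neutrophil genes (4 measured) a median of 0.013 with camera pointing down (adjusted p = 0.646).

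Hox genes record the level of the cord that was taken. Thoracic Hox genes (9 measured, none past) had a median of 0.17, with Hoxb7 at 121 ± 8.14 TPM in WT and 141 ± 10.2 TPM in the null (SD, n = 3 each). Cervical and brachial Hox genes (10 measured, none past) had a median of -0.0064. Of the lumbosacral genes 3 of 10 were measured and none passed: Hoxa10 was at 28.8 ± 5.29 and 42.3 ± 7.96 TPM, and Hoxd10 was at 35.82 TPM in WT replicate 1 and 7.67 to 12.49 TPM in the other libraries. Camera's adjusted p was 0.0151 for the thoracic list, 0.991 for the cervical list and 0.784 for the lumbosacral list, whose median of -0.12 went against its mean of 0.046. The thoracic call was lost with an estimated correlation (adjusted p = 0.417), without WT replicate 3 (0.190) and without null replicates 1 (0.0677) or 3 (0.0532). Without WT replicate 1 the cervical median was 0.17 (adjusted p = 0.00309) and the lumbosacral median 0.40 (adjusted p = 0.00348).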

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

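The scaling, robust, array-weight and protein-coding settings were chosen after the results were seen, the rest before. No gene passed in the main limma test, and 1 did with a pseudocount of 0.1, 1 with robust empirical Bayes (Gm43493 in both), 10 with array weights (9 lower, among them Myt1, Gpr17, Bcas1, Nkx2-2, Mbp, Mobp and Tnr) and 0 to 7 with 1 library left out. Over all settings, 0 to 10 calls stood beside 718 to 1838 genes at an unadjusted p under 0.05. The change of Myt1 was -1.0 with array weights, past the threshold by limma (adjusted p = 0.0407), while over all settings the adjusted p lay between 0.0407 and 0.699 (changes of -1.06 to -0.93 with 1 library left out). The number of lists called was 0 with an estimated correlation, 1 by fry and 11 to 17 with 1 library left out. The myelinating (-0.66), committed (-0.51) and precursor (-0.037) medians do not move with the set test, but with an estimated correlation all 3 lost their call, and by fry the myelinating (adjusted p = 0.0759) and precursor (0.228) lists did. With 1 library left out these medians ranged over -0.71 to -0.58, -0.57 to -0.45 and -0.13 to -0.024, and members that fell, adjusted over the list alone, over 13 to 14, 6 to 12 and 2 to 4. Precursor members that fell numbered 7 without a filter and 8 with array weights.

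With 1 library left out the median of 16 lists changed sign at least once: 10 without a call before or after, and 6 with one. Without WT replicate 1 it was -0.27 for meninges (range over the libraries -0.27 to 0.34), 0.17 for cervical Hox (-0.062 to 0.17), 0.40 for lumbosacral Hox (-0.26 to 0.40) and 0.067 for mitochondrial genes (-0.18 to 0.067). It was -0.30 for interferon without WT replicate 3 (-0.30 to 0.18) and -0.59 for muscle without null replicate 3 (-0.59 to 0.94). Mitochondrial genes turned to 0.026 with array weights, which weigh WT replicate 1 least (0.363). The cause was not tested for any of these changes. Of 1609 values of 95 named genes, 1599 kept direction and side of the threshold, 8 came to pass, 2 changed sign without passing and 0 reversed. None of these genes passed in the main test, so keeping the side of the threshold meant still not passing. Many were named for a small p, or after their values were seen, in these same samples, which made a change of direction unlikely beforehand. The count is therefore not an independent test of how stable these genes are. With replicate number as a block 0 genes passed and 1140 had an unadjusted p under 0.05; the cholesterol list lost its call (0.0565) and no other list or Myt1 changed call. No pairing by number was seen: same-numbered deviations correlated at 0.031, -0.070 and 0.061, and 2 of 6 samples correlated best with their own number. A shared litter or batch with a small effect is not excluded by this. Tests that need counts (the planned main test, its other scalings and voom) were not run. Depth is unknown, so what it limits cannot be stated.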

Other observations

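The tests of WT replicate 1, of the whole lineage, of the sensory list, of genes near Myt1 and of gene families were chosen after the results were seen; the splits of the samples and the Schwann cell test were set out before, but its fit of list means was added after. Outside the fixed lists, the genes with the smallest p whose groups did not overlap, leaving out unnamed gene models such as Gm43493, were picked after their values were seen, 8 lower and 8 higher, and none passed an adjusted p of 0.05 in limma. The lower ones included Aatk, a kinase of neural tissue, at 70.1 ± 0.643 TPM in WT and 51.6 ± 1.22 TPM in the null (SD, n = 3 each; log2 change -0.44, adjusted p = 0.140). Plxnb3, a semaphorin receptor, was at 4.52 ± 1.54 and 0.880 ± 0.155 TPM, 5.14-fold lower, and Sema4d, a semaphorin, at 24.3 ± 2.49 and 16.1 ± 0.875 TPM. Fxyd1, Parvb, Vxn, Ecel1 and Tubb4a were the others. Those higher included Dmrta1, a transcription factor, at 0.693 ± 0.168 and 3.11 ± 0.845 TPM, 4.49-fold higher, with Matr3, Dnajc24, Ube2e3 and Snrpd1.

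Also higher were Neurod1, at 4.39 ± 0.350 TPM in WT and 7.26 ± 0.223 TPM in the null (SD, n = 3 each), and Neurod6, at 28.7 ± 1.6 and 38.7 ± 2.85 TPM, both neurogenic bHLH factors. With Neurod2 (14.8 ± 0.286 and 19.0 ± 1.85 TPM) and Atoh8 (2.88 ± 0.429 and 3.55 ± 0.910 TPM) they form a family of 4 measured members with a median of 0.38, all higher on average and 3 above every WT sample. Camera gave an adjusted p of 6.09e-05 over the 8 families tried, fry 0.00388, and with an estimated correlation the adjusted p was 0.0942; the family was picked because Neurod1 and Neurod6 had been seen, so this is not independent evidence. Zinc finger genes named Zfp (355 measured, 285 higher) had a median of 0.14 (camera adjusted p = 1.2e-05; 0.753 with an estimated correlation), and 0.05 without WT replicate 1. Ribosomal protein genes (77 measured) had a median of 0.042 and a camera adjusted p of 0.00312 (0.753 with an estimated correlation), and a median of 0.024 without WT replicate 1 (0.0242). Under the 3 other scalings these medians kept their sign, at 0.35 to 0.37 for the neurogenic family, 0.11 to 0.13 for Zfp genes and 0.015 to 0.033 for ribosomal proteins. The other 5 families were not called by camera.

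Dividing 6 samples into 3 and 3 makes 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest other split 5, so all 10 splits gave as many. It gave 1189 genes at an unadjusted p under 0.05 against 1250 in the highest other split (2 of 10 as large), and 14 lists by camera against 17 (2 of 10 as large). Every other split sets 2 samples of 1 genotype and 1 of the other against the rest, so it carries part of any genotype difference and is not a reference without change. The difference in the mean of the committed list was 0.744 in the real split and 0.343 in the highest other (1 of 10 as large).

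The fall of the myelinating and committed lists was weighed against a single high WT library, peripheral glia and loss of the whole lineage. Without WT replicate 1 the median of the 37 members was -0.57, against -0.65 with it, which argues against that library as the whole cause. The committed minus precursor difference changed by -0.58 with an SD of at most 0.021 within a group (exact permutation p = 0.1, the smallest possible). This argues against an equal fall in RNA of both lists. Bulk tissue does not show which cells made the precursor-list RNA, and RNA from cells outside the lineage would dilute a fall. An equal loss of cells of all stages is therefore not excluded. With the mean of 11 Schwann cell genes as a covariate the median was -0.54, which met the bound set before (camera adjusted p = 2.02e-06 and 9.52e-08; 0.639 for both with an estimated correlation), while the Schwann median went from -0.51 to -0.043, the myelinating from -0.66 (median SE 0.22) to -0.57 (0.31) and the committed from -0.51 (0.14) to -0.37 (0.23), and members that fell, adjusted over the list alone, went from 14 to 1 and from 9 to 4 as the errors grew. That bound takes members as nearly independent, and in a fit of the mean of each list the committed change went from -0.74 (95% interval -0.92 to -0.57) to -0.78 (-1.14 to -0.42) with the covariate, which argues against Schwann cell RNA as its whole cause, but the myelinating change from -0.94 (-1.39 to -0.49) to -0.68 (-1.39 to 0.031), so for that list Schwann cell RNA and genotype cannot be told apart with 6 libraries; the age and dissection of each animal were not tested.

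The low sensory ganglion list may come from differing amounts of ganglion left on the cord. Its members' deviations from their group means had a mean pairwise correlation of 0.728, above the highest of 1000 random lists (0.535), as for muscle (0.753), with 0.366 for the myelinating list. Lists not named for adjoining tissue also exceeded 0.535, among them mitochondrially encoded (0.628), hypoxia (0.609) and DNA replication (0.595) genes. A high value therefore does not single out ganglion tissue as the source. Only 1 of the 3 null libraries, null replicate 3, lay below every WT library in the list mean, so that library may carry much of the difference; without it the median was -0.46 (camera adjusted p = 0.00661). A change in the ganglia themselves stays open, untested.

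Genes near Myt1 could differ because of strain DNA carried along with the targeted allele. Of 69 tested genes within 5 Mb, 7 (10.1%, exact 95% interval 4.18% to 19.8%) had an unadjusted p under 0.05, against 7.44% of 15865 elsewhere (Fisher's exact test, one-sided p = 0.254). The interval holds both the share elsewhere and double it (14.9%), so flanking DNA and chance cannot be told apart with 69 genes. Bcas1 (from 170346991), Matn4 (from 164389393) and Nkx2-2 (from 147177546) also lie on chromosome 2, outside this window, and were counted as elsewhere. Of the genes picked outside the lists, Dnajc24 (from 105966709), Neurod1 (from 79452521) and Ube2e3 (from 78868124) do so too. Whether flanking DNA reaches them was not tested.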
